A study of Rattus norvegicus with 12 samples.

How the data were processed

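Gene expression was measured in the pituitary and the hypothalamus of male Wistar rat fetuses on gestational day 20, after the dams had received TCDD (2,3,7,8-tetrachlorodibenzo-p-dioxin, the prototype dioxin) in corn oil, or had served as controls, on gestational day 15. Per the series text the dose was 1 µg/kg. The sample labels give the same figure in mg/kg, and the conflict was left as it stands because no value here depends on it. The 12 samples form 4 groups of 3, one for each tissue and treatment, and each group was read from the sample labels. The labels do not say that the samples of a group came from separate dams or litters, so p-values measure the spread between these samples, which may be technical. Each sample was hybridised to a RatRef-12 BeadChip, a 1-colour Illumina array, as biotin-labelled cRNA made with a TotalPrep kit from column-purified total RNA, per the labels' protocols.

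The deposited table of non-normalized values holds 1 summarised bead intensity per probe and array, per the file headers, and the values are positive on every array, with no sign of an earlier background subtraction or scaling. Beside each intensity the authors deposited a detection p-value, per the file headers. The scanner software is not given in the sources used here. A second table deposited by the authors holds processed values on a scale that resembles log2. From the values, its columns rank the probes of each array exactly as the raw intensities do, and the arrays of a tissue share 1 distribution while the tissues do not, with a median of 7.91 in the hypothalamus and 7.89 in the pituitary. The exact transform behind it stays unknown, no centring of genes was seen, and it served only as an alternative.

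Intensities of all 22523 probes were background-corrected and quantile-normalized over the 12 arrays with neqc of limma 3.58.1 in R 4.3.3, which estimates the background from the detection p-values, adds an offset of 16 and returns log2 values. Quantile normalization gives both tissues the same distribution, and the offset pulls the fold changes of dim probes towards 0. Probes with a detection p below 0.05 on at least 3 arrays were tested, which kept 13018 and left out 9505. A single limma model with 4 group means and no covariates was fitted to the 12 arrays, so that all groups shared 1 estimate of the spread, with 8 residual and 4.19 prior degrees of freedom. Moderated tests were two-sided, with Benjamini-Hochberg adjustment over the tested probes of each comparison and a threshold of 0.05. The comparisons were TCDD against control in each tissue, the difference of these effects between the tissues, and pituitary against hypothalamus in controls. Raw medians ran from 92.5 to 120.8 intensity units and the share of detected probes from 47.4% to 54.5% per array. The number of arrays limits the precision.

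Gene symbols came from a table of the platform's annotation, which names 1 symbol for 13793 probes, several for 0 and none for 8730. Of the tested probes, 9359 carried a symbol, for 9178 genes. Symbols were checked through their Entrez identifiers. A probe without a symbol is unnamed here, and its gene is not guessed. A gene with several probes in a list was represented by the probe with the highest mean signal. Where a group of arrays never exceeded background for a probe, the fold is given as a bound: the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal among detected probes and the probe's own signal.

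The 24 gene lists covered AhR targets, gonadotroph and other anterior pituitary hormone genes, hypothalamic neuropeptides and transcription factors, steroid and thyroid hormone receptors, histone deacetylases and acetyltransferases, cell cycle, lipoate and TCA cycle, cholesterol synthesis, NRF2, ER stress and heat shock, and immediate early genes. They also held markers of blood, endothelium, microglia, glia, oligodendrocytes, neurons, other forebrain, mesenchyme and bone, skeletal muscle and choroid plexus, and Y-linked genes. The lists hold 443 genes, of which 359 had a named probe and 312 were tested, and 23 lists had the 4 tested genes required. Lists were tested with camera at a preset correlation of 0.01, two-sided, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Members were also counted with p-values adjusted over the list alone.

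The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. For each TCDD comparison the text names, among symbol-bearing probes that passed, the 10 with the largest rise and the 10 with the largest fall, or where fewer pass the genes of smallest p up to 6 per direction. It also names a fixed set of genes (Cyp1a1, Cyp1b1, Ahrr, Tiparp, Nqo1, Ahr, Lhb, Fshb, Cga, Gnrhr, Gh1, Prl, Tshb, Pomc, Gnrh1, Kiss1, Hdac1 and Hdac2) and up to 4 list members that passed, or 2 members of smallest p where none did. For the tissue comparison the 10 largest differences in each direction are named, and for the difference of effects the 5 smallest p-values in each direction. Tiparp and Gh1 had no named probe and are not analysed here. Predicted loci were passed over in the ranking by size.

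The procedure was tested on simulated data for the pituitary comparison, with 13018 probes of which 200 were changed. It recovered 46% of those changed by 1.41-fold, 92% at 2-fold and 100% at 4-fold and 8-fold, with 7 false calls, and called 0 lists in unchanged data. The simulated noise was independent between probes, so that last result does not cover lists whose genes vary together. Alternatives left out the background correction, took the authors' values, scaled arrays to a common median, fitted the tissues separately, dropped or tightened the filter, used an intensity trend with robust moderation, array weights, a replicate block, a fold threshold of 1.5, or left out each array in turn. Other splits of the samples were refitted, up to 100 per comparison.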

Results

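Transcripts were measured on 12 Illumina rat arrays, 3 each from control and TCDD-exposed pituitaries and from control and TCDD-exposed hypothalami of male fetuses on gestational day 20. TCDD is a dioxin that acts through the aryl hydrocarbon receptor (AhR), a ligand-activated transcription factor. Per array, 47.4% to 54.5% of the 22523 probes were detected above background. Correlations of normalized values across probes, which are not independent replicates, were 0.984 to 0.994 within a group and 0.834 to 0.885 between tissues. Between control and TCDD arrays of the same tissue they were 0.981 to 0.994, close to the range within a group. Fold changes are log2 values of TCDD over control with the standard error of the limma model, and each group had 3 arrays.

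The pituitary comparison bears on the study's stated question, which genes lie behind a loss of gonadotropin β-subunits in exposed fetuses. The strongest rises were in targets of AhR. Cyp1a1, a cytochrome P450 that metabolises aromatic hydrocarbons, was not above background on any control array and rose to a normalized log2 level of 11.34 ± 0.24 (SD, n = 3), at least 57.4-fold higher (adjusted p = 1.11e-11). Ahrr, the repressor of AhR, likewise rose from below background by at least 10.9-fold (adjusted p = 1.87e-11). Nqo1, a quinone reductase, rose by 1.69 ± 0.11 (adjusted p = 9.00e-06) and Cyp1b1, another cytochrome P450, by 1.87 ± 0.32 (adjusted p = 0.0193). Of 7 tested AhR target genes, 6 rose over all probes and 6 adjusted over the list alone, with a median of 1.69, also with the 4 genes below background in controls at their lower bounds (camera adjusted p = 6.35e-23, and adjusted p = 0.00182 with an estimated correlation). The other risers were Cyp1a2, at least 1.08-fold, and Ugt1a6, a glucuronosyltransferase whose transcript shares exons with its gene family, at least 2.40-fold. Both lay below background in controls. The remaining gene of the 7 was Ahr itself, the receptor gene, which the list also holds. At −0.17 ± 0.15 it did not pass (adjusted p = 0.747). The Cyp1b1 call was lost without pituitary control replicate 1 (adjusted p = 0.0760), control replicate 2 (0.0966), TCDD replicate 1 (0.0950) or TCDD replicate 2 (0.0617), and with an intensity trend (0.0704), within 1.98e-04 to 0.0966 over all alternatives.

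The mRNAs of both gonadotropin β-subunits fell. Fshb, which encodes the β-subunit of follicle-stimulating hormone, went from a log2 level of 9.24 ± 0.69 in controls to 5.92 ± 0.68 with TCDD (SD, n = 3), where 2 of 3 arrays detected it, and fell by 3.32 ± 0.33 (SE, adjusted p = 3.40e-04). Lhb, the β-subunit of luteinizing hormone, fell by 1.81 ± 0.21 (adjusted p = 0.00135), from 11.61 ± 0.46 to 9.80 ± 0.07. Gnrhr, the gonadotroph receptor for gonadotropin-releasing hormone, fell by 1.47 ± 0.21 (adjusted p = 0.00606), from 8.62 ± 0.59 to 7.16 ± 0.08. Among 12 tested gonadotroph genes these 3 fell over all probes. Adjusted over the list alone the same 3 fell and 3 rose: Egr1 (0.76), an immediate early transcription factor, Fst (0.50), the activin antagonist follistatin, and Acvr2a (0.39), an activin receptor. Without pituitary TCDD replicate 5 Egr1 (0.49) lost its call adjusted over the list alone (adjusted p = 0.133). With all arrays the list had a median of 0.02 and a mean of −0.41, and its camera test gave adjusted p = 0.638. The probe for Cga, the shared α-subunit, lay near background on every array and was not tested, so it gives no measure of that transcript. With each tissue normalized and fitted alone, Fshb (−3.36) and Gnrhr (−1.45) kept their size but gave adjusted p = 0.0522 and 0.136, the highest over their alternatives, whose lowest were 3.74e-05 and 5.62e-06.

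Genes of the other anterior pituitary cell types did not shift as a group. Of 13 tested, 2 rose and 1 fell, both over all probes and adjusted over the list alone, with a median of −0.03 and a mean of 0.04 (camera adjusted p = 0.739). Rxrg, a retinoid X receptor, rose by 0.77 ± 0.11 (adjusted p = 0.00609) and Pcsk2, a prohormone convertase, by 0.82 ± 0.14 (adjusted p = 0.0187). Ghrhr, the receptor for growth hormone-releasing hormone, fell by 0.99 ± 0.16 (adjusted p = 0.0152). The hormone genes Tshb (−0.26 ± 0.37), Prl (−0.19 ± 0.28) and Pomc (0.05 ± 0.13) did not pass, with adjusted p = 0.856, 0.867 and 0.917. The Ghrhr and Pcsk2 calls were lost without pituitary control replicate 1 (adjusted p = 0.0731 and 0.0966), control replicate 2 (0.0777 and 0.0526) or TCDD replicate 1 (0.0769 and 0.0950), and that of Pcsk2 also without TCDD replicate 2 (0.0577). Fitted by tissue they gave 0.115 and 0.0868, and the lowest over their alternatives were 0.00231 and 0.00512. A replicate block ended the calls of Rxrg (adjusted p = 0.130) and Pcsk2 (0.213).

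**Figure D1:**
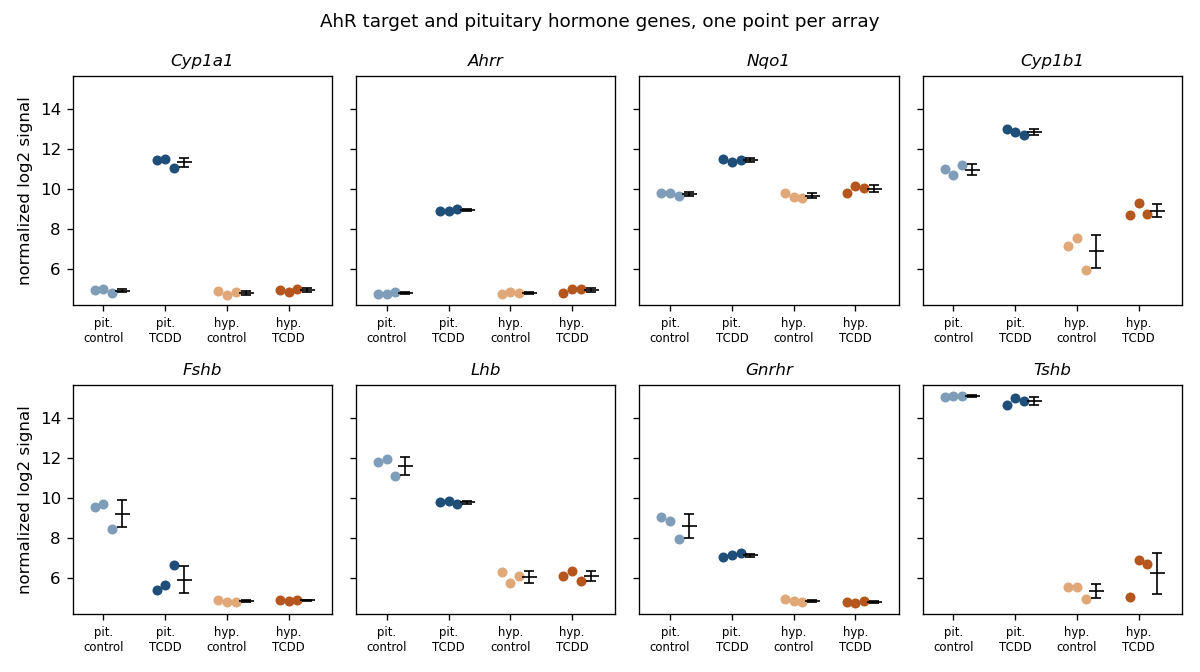
Normalized log2 signal of Cyp1a1, Ahrr, Nqo1, Cyp1b1, Fshb, Lhb, Gnrhr and Tshb in the 4 groups, with 1 point per array and black bars and whiskers for the mean ± SD of 3 arrays. In the pituitary Fshb averaged 9.24 in controls and 5.92 with TCDD, while Cyp1a1 averaged 4.94 and 11.34.

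Genes outside these groups were among the largest changes. Myh7, the slow and cardiac β-myosin heavy chain, rose by 2.51 ± 0.12 (adjusted p = 2.52e-07), Alox15, a lipoxygenase, by 2.47 ± 0.26 (adjusted p = 4.55e-04), and Aldh1a1, a retinaldehyde dehydrogenase, by 1.98 ± 0.26 (adjusted p = 0.00286). The olfactory receptor Or5m8 (1.86) and Bloc1s1 (1.42), a subunit of a lysosome biogenesis complex, rose as well. Tpsab1, a mast cell tryptase, fell by 2.82 ± 0.35 (adjusted p = 0.00248), and the mast cell protease Mcpt10 fell at least 1.97-fold, to below background (adjusted p = 7.37e-05). Dapl1 fell by 1.89 ± 0.18 (adjusted p = 2.45e-04), Serpina3c by 1.61 ± 0.24 (adjusted p = 0.00746) and Panx3, a pannexin channel of skeletal tissue, by 1.91 ± 0.37 (adjusted p = 0.0390). Serpina3c gave adjusted p = 0.136 when the tissues were fitted separately, and 0.00171 at the lowest over its alternatives. A replicate block ended the calls of Serpina3c (adjusted p = 0.281) and Tpsab1 (0.106). Panx3 passed without pituitary control replicate 3 and lost its call without any other single array (adjusted p = 0.0542 to 0.167), and also with the authors' values (0.0703), no filter (0.0810), an intensity trend (0.0846) or separate fits (0.201).

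Skeletal muscle markers, fixed as a sign of attached tissue, were lower in TCDD pituitaries. Of 10 tested, 8 fell adjusted over the list alone and 4 over all probes, with a median of −0.60. The list gave camera adjusted p = 5.17e-09 and fry adjusted p = 0.00603, but camera adjusted p = 0.0948 with an estimated correlation. The 4 were Myl11 (−1.37 ± 0.19, adjusted p = 0.00435), Ckm (−1.40 ± 0.26, 0.0296), Tnnc2 (7.94 ± 0.30 in controls and 6.94 ± 0.32 with TCDD as log2 level ± SD, 0.0284) and Tnnt3 (−0.52 ± 0.10, 0.0468), which encode a myosin light chain, muscle creatine kinase and fast troponins. The median level of the markers on the control arrays was 6.75, 7.05 and 7.47, and on the TCDD arrays 6.40, 6.14 and 6.47. Myl11 gave adjusted p = 0.107 when the tissues were fitted separately. Tnnt3 lost its call without any single array other than pituitary TCDD replicate 1 (adjusted p = 0.0573 to 0.215), Ckm without any of pituitary control replicates 2 and 3, pituitary TCDD replicates 1 and 2, hypothalamus control replicates 3 and 5 and hypothalamus TCDD replicate 1 (0.0514 to 0.130), and Tnnc2 without pituitary control replicates 2 or 3, pituitary TCDD replicates 1 or 2, or hypothalamus TCDD replicate 1 (0.0505 to 0.134). Separate fits ended the calls of Tnnc2 (0.153), Ckm (0.198) and Tnnt3 (0.156), no filter that of Ckm (0.0601), and the authors' values (0.0594), no background correction (0.109), median scaling (0.0575) and an intensity trend (0.0846) that of Tnnt3.

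Cell cycle genes were slightly lower with TCDD. Of 25 tested, 24 had a negative log2 fold, with a median of −0.35, and 8 fell adjusted over the list alone, among them Mcm5 (−0.46), Plk1 (−0.47), Ttk (−0.41) and Mcm6 (−0.37), which act in DNA replication and mitosis. None passed over all probes (Mcm5 adjusted p = 0.0958). The list passed by camera (adjusted p = 5.61e-10) but gave adjusted p = 0.325 with an estimated correlation and 0.0603 by fry. Cholesterol synthesis genes had a median of −0.22 over 16 tested, and 2 fell adjusted over the list alone, Idi1 (−0.65) and Msmo1 (−0.41), with 0 past the limma threshold over all probes. That list gave camera adjusted p = 0.00337, but adjusted p = 0.925 with an estimated correlation and 0.480 by fry. It lost its camera call without pituitary TCDD replicate 1 (median −0.10, adjusted p = 0.274) or TCDD replicate 2 (median −0.15, adjusted p = 0.0761). Pituitary TCDD replicate 5 stood apart from the other pituitary arrays, with 220 genes more than 1 log2 unit above the mean of the 5 others and 40 as far below. Without it the cell cycle median was −0.30 with 0 falls adjusted over the list alone by limma, and the cholesterol median was −0.35 with 9 such falls, 3 of them over all probes, including Idi1 (−0.91, adjusted p = 0.00611).

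Neuron markers moved with that same array. Over 14 tested the median was 0.36 and 0 passed by limma, over all probes or adjusted over the list alone (camera adjusted p = 0.115). Without TCDD replicate 5 the median was −0.17, while without TCDD replicate 1 (0.48, adjusted p = 1.76e-04) or TCDD replicate 2 (0.47, adjusted p = 0.00520) the list passed upward. The 2 markers of smallest p were Snap25 (0.36) and Celf4 (−0.52), which encode a synaptic vesicle fusion protein and an RNA-binding protein of neurons. Oligodendrocyte markers had a median of 0.12 over 8 genes (camera adjusted p = 0.190), of which Mbp, myelin basic protein, rose by 0.84 adjusted over the list alone. Without TCDD replicate 5 the oligodendrocyte median was 0.20, Mbp rose by 0.50, and Olig1 (−0.54) and the neuron markers Nefl (−0.94) and Celf4 (−0.68) fell adjusted over their lists alone.

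**Figure D2:**
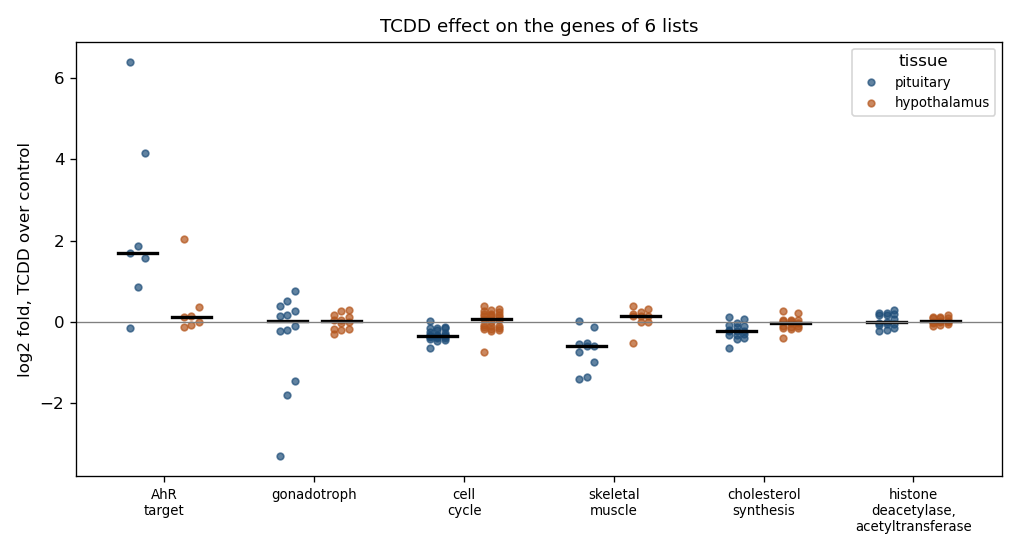
Log2 fold of TCDD over control for the genes of 6 fixed lists, with 1 dot per gene, blue for pituitary and orange for hypothalamus, and a black line at each median. In the pituitary the medians were 1.69 for AhR targets, 0.02 for gonadotroph genes, −0.35 for cell cycle genes, −0.60 for skeletal muscle markers, −0.22 for cholesterol synthesis genes and −0.01 for histone deacetylases and acetyltransferases.

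The remaining lists did not pass in the pituitary. Histone deacetylases and acetyltransferases had a median of −0.01 and a mean of 0.03 over 15 genes (camera adjusted p = 0.638), with Hdac1 at −0.22 ± 0.13 (adjusted p = 0.573) and Hdac2 at −0.15 ± 0.08 (adjusted p = 0.514). Lipoate and TCA cycle genes had a median of 0.00 over 20 genes (adjusted p = 0.990), hypothalamic neuropeptide genes 0.02 over 32 (0.881), hypothalamic transcription factors −0.02 over 13 (0.881), and steroid and thyroid hormone receptors −0.02 over 10 (0.990). NRF2 and oxidative stress genes had a median of −0.03 over 16 (0.912), with Nfe2l2, which encodes NRF2, up by 0.67 adjusted over the list alone. Without TCDD replicate 5 the Nfe2l2 estimate was 0.68, and its call adjusted over the list alone was lost. ER stress and heat shock genes had a median of −0.04 over 15 (0.609), and Sdf2l1, a protein of the endoplasmic reticulum, fell by 0.67 ± 0.11 over all probes (adjusted p = 0.0113). Immediate early genes had a median of 0.13 over 13 (0.638), with Nr4a3 lower (−0.46) adjusted over the list alone. Medians of blood (−0.02, 0.812), endothelial (−0.11, 0.881), microglia (−0.18, 0.242), glial (0.05, 0.881), forebrain (0.01, 0.935), mesenchyme and bone (0.02, 0.881) and choroid plexus (−0.20, 0.812) markers did not pass. The mean of the endothelial (0.02), glial (−0.00), mesenchyme (−0.07) and forebrain (−0.04) lists had the other sign. Without TCDD replicate 5 several of these medians changed sign, to −0.01 for immediate early genes, 0.02 for endothelial, −0.03 for glial and −0.02 for forebrain markers, −0.07 for neuropeptide genes, 0.06 for steroid and thyroid hormone receptors, −0.03 for TCA cycle genes, and 0.01 for NRF2 genes and for histone deacetylases and acetyltransferases, and the mesenchyme median was 0.08. No Y-linked gene had a named probe.

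Within those lists Vwf, the endothelial von Willebrand factor, rose by 1.08 ± 0.20 over all probes (adjusted p = 0.0315), and Ibsp (−1.75), Trh (−1.06) and Folr1 (−0.39) fell adjusted over the list alone. Ibsp encodes a bone matrix protein and Trh thyrotropin-releasing hormone, and over all probes they gave adjusted p = 0.0504 and 0.0717. Gnrh1 (−0.19 ± 0.22) did not pass and Kiss1 was not above background. Ibsp passed without pituitary control replicate 3 (adjusted p = 1.63e-04), and Trh without that array (0.0439) or without TCDD replicate 5 (0.0471). The Sdf2l1 call was lost without pituitary control replicates 1 (adjusted p = 0.0596) or 2 (0.0517) or TCDD replicate 1 (0.0636), and the Vwf call without pituitary control replicates 1, 2 or 3, pituitary TCDD replicates 1 or 2, hypothalamus control replicate 3 or hypothalamus TCDD replicate 1 (0.0512 to 0.153). Both were lost with separate fits (0.0926 and 0.107), and Vwf with no filter (0.0601).

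In total 87 probes passed in the pituitary, 50 higher and 37 lower, of which 79 carried a symbol. At an unadjusted p below 0.05 there were 1501, where chance gives 651 on average. The count was 51 without pituitary control replicate 1, 43 without control replicate 2, 44 without TCDD replicate 1, and 92 without TCDD replicate 5, of which 65 were shared. It was 218 with the authors' values, 231 with array weights and 26 with the tissues fitted separately.

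In the hypothalamus, the source of the releasing hormones that drive the pituitary, few probes passed for TCDD against control. At an unadjusted p below 0.05 there were 1422, where chance gives 651 on average, and 986 to 2127 on leaving out 1 array. The few calls do not show a lack of change. The excess does not show a change either, as probes vary together and it was not counted over other splits of the samples. The tests passed 3 probes, all without a symbol here: ILMN_1364999 rose by 0.62 (adjusted p = 0.0405), and ILMN_1371022 (−0.85, adjusted p = 0.0337) and ILMN_1357002 (−1.12, adjusted p = 0.0195) fell. Cyp1b1 had the largest estimate among AhR targets, 2.04 ± 0.32, which missed the threshold over all probes (adjusted p = 0.111) but passed adjusted over the list alone (adjusted p = 2.39e-04). Its level was 6.89 ± 0.84 in controls and 8.93 ± 0.32 with TCDD (SD, n = 3). Nqo1, at 0.35 ± 0.11, also passed adjusted over the list alone (adjusted p = 0.0289). Cyp1a1 and Ahrr were not above background in either group, and Ahr did not pass (−0.13 ± 0.15). The AhR list had a median of 0.13 over 7 genes (camera adjusted p = 0.114). Without hypothalamus control replicate 5, Cyp1b1 passed over all probes (1.57, adjusted p = 0.0291, within 0.0291 to 0.507 over all alternatives), and with the authors' values its estimate was 0.79.

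After Cyp1b1, the named genes of smallest p did not pass, with adjusted p between 0.235 and 0.239. Lower estimates were those of Slc40a1 (−0.65), the iron exporter ferroportin, Car4 (−1.25), a carbonic anhydrase, Zfp763 (−0.56), Aloxe3 (−0.65), Serpinb6b (−0.68) and Itgb1bp2 (−0.76). Higher estimates were those of Loxl1 (0.91, and 0.36 by a second probe), a lysyl oxidase, Tspan9 (0.42), Agpat4 (0.44), Ocel1 (0.44) and Stk32b, at least 1.31-fold. Car4 passed without hypothalamus TCDD replicate 1 (−1.63, adjusted p = 0.00188), as did Tshb (0.88 ± 0.37, adjusted p = 0.417 with all arrays), at 1.46 and adjusted p = 0.0345. Gnrh1 (−0.24 ± 0.22), Pomc (−0.02), Prl (−0.11), Lhb (0.05), Hdac1 (−0.01) and Hdac2 (−0.00) did not pass. Fshb, Gnrhr, Kiss1 and Cga were not above background.

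No list passed in the hypothalamus by camera, 6 had an unadjusted p below 0.05, and 0 passed by fry. Adjusted over the list alone, Gad2 (−0.39), a GABA-synthesising enzyme, was the single faller among 32 neuropeptide and transmitter genes, and Hspb1 (0.83), a heat shock protein, and Alas2 (0.76), an erythroid haem enzyme, rose in their lists. Of 10 skeletal muscle markers, 1 also rose adjusted over the list alone. The lowest adjusted p of 0.114 was shared by AhR targets, other anterior pituitary genes (median 0.17), hypothalamic transcription factors (0.17), immediate early genes (0.15) and blood markers (0.07). Lists passed on leaving out hypothalamus control replicate 1 (AhR and anterior pituitary, adjusted p = 0.0468), control replicate 3 (immediate early, blood, glial, and mesenchyme and bone, 0.0469), TCDD replicate 1 (AhR, anterior pituitary and blood, 0.0404) or TCDD replicate 3 (hypothalamic transcription factors, 0.0317, with immediate early and blood, 0.0338). With arrays scaled to a common median 7 lists passed, among them AhR targets (adjusted p = 0.00233).

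Of the 3 probe calls, 1 remained without hypothalamus control replicate 1, hypothalamus TCDD replicate 3, pituitary TCDD replicate 1 or pituitary TCDD replicate 5. By limma 0 passed without hypothalamus control replicate 3, hypothalamus TCDD replicate 4, pituitary control replicates 1, 2 or 3, or pituitary TCDD replicate 2, with 986 to 1322 at an unadjusted p below 0.05, and 16 passed without hypothalamus control replicate 5. With all arrays, 1422 probes had an unadjusted p below 0.05, where chance gives 651 on average.

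The difference of the TCDD effect between the tissues was tested directly, as pituitary minus hypothalamus. The larger pituitary rises were those of Cyp1a1 (6.28 ± 0.17, adjusted p = 9.42e-10), Ahrr (4.02 ± 0.12, adjusted p = 1.80e-09), Myh7 (2.38 ± 0.17, adjusted p = 2.75e-05), Or5m8 (1.75 ± 0.18, adjusted p = 0.00178) and Bloc1s1 (1.51 ± 0.17, adjusted p = 0.00267). For Cyp1a1 and Ahrr these are fitted values that rest on 3 groups at background level. The pituitary effect was more negative for Fshb (−3.36 ± 0.47, adjusted p = 0.0127), Tpsab1 (−3.28 ± 0.50, 0.0221), Lhb (−1.86 ± 0.30, 0.0270), Dapl1 (−1.66 ± 0.26, 0.0221) and Mcpt10 (−1.36 ± 0.17, 0.00546). Fshb and Mcpt10 were not above background on any hypothalamus array, and Tpsab1 only on 1 TCDD array there. A fall of these 3 genes could not be measured in the hypothalamus, so their differences rest on the pituitary change alone. Nqo1 differed by 1.34 (adjusted p = 0.00385), while Cyp1b1 (−0.17, adjusted p = 0.904) and Gnrhr (−1.43, adjusted p = 0.116) did not pass. Calls were lost for Fshb without hypothalamus control replicate 3 (adjusted p = 0.0526), for Tpsab1 without hypothalamus control replicates 1, 3 or 5, pituitary control replicate 2 or pituitary TCDD replicate 2 (0.0518 to 0.0699), for Dapl1 without hypothalamus control replicate 3, pituitary control replicates 1 or 2, or pituitary TCDD replicate 1 (0.0553 to 0.0779), and for Lhb without hypothalamus control replicates 3 or 5, hypothalamus TCDD replicates 1 or 3, pituitary control replicates 1 or 2, or pituitary TCDD replicates 1 or 2 (0.0612 to 0.0851). With the authors' values the Fshb call was also lost (−1.48, adjusted p = 0.0501), and with no filter on dim probes the Lhb call (adjusted p = 0.0602), where their alternatives ran from 5.26e-04 to 0.0526 and from 0.00241 to 0.108. A replicate block ended the calls of Bloc1s1 (adjusted p = 0.0932), Mcpt10 (0.199), Tpsab1 (0.224), Dapl1 (0.0862) and Lhb (0.108).

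As groups, AhR targets differed most, with a median difference of 1.34 and 5 of 7 genes higher adjusted over the list alone (camera adjusted p = 5.16e-15, and adjusted p = 0.00798 with an estimated correlation). Skeletal muscle markers had a median of −0.82, with 5 of 10 lower adjusted over the list alone, and cell cycle genes a median of −0.32, with 6 of 25 lower. Their camera tests gave adjusted p = 1.03e-07 and 2.82e-07, but adjusted p = 0.135 and 0.600 with an estimated correlation. By fry these lists gave adjusted p = 0.0195 and 0.204. Gonadotroph genes had 3 of 12 lower and 2 higher adjusted over the list alone, with a median of 0.04 and a mean of −0.41 (camera adjusted p = 0.636). Further lists passed without a single array: cholesterol synthesis without pituitary TCDD replicate 5 (median −0.39, adjusted p = 4.07e-06), neuron markers without pituitary TCDD replicate 1 (0.0282), hypothalamic transcription factors without pituitary control replicate 2 (0.00909), mesenchyme and bone without hypothalamus control replicate 3 (0.0496), and blood markers without hypothalamus control replicate 3, hypothalamus TCDD replicate 1 or pituitary control replicate 2 (0.00837 to 0.0496).

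In total 26 probes differed, 16 with the higher and 10 with the lower effect in the pituitary, against 1538 at an unadjusted p below 0.05. The count was 16 without hypothalamus control replicate 1, 10 without hypothalamus control replicate 3, 16 without hypothalamus TCDD replicate 4, 17 without pituitary control replicate 1, 13 without pituitary control replicate 2 and 17 without pituitary TCDD replicate 1.

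The control tissues were compared to check the dissection, as pituitary minus hypothalamus. Pituitary transcripts were far higher in the pituitary: Tshb, the β-subunit of thyrotropin (9.75 ± 0.37), Prl, prolactin (6.29 ± 0.28), and the transcription factors Pitx1, at least 141-fold (adjusted p = 3.22e-12), and Pou1f1, at least 36.3-fold. Pomc (5.30), Lhb (5.54), Fshb (at least 12.7-fold) and Gnrhr (at least 8.28-fold) were higher too, as were the connective tissue genes Col8a1 (7.36), Col1a1 (6.85), Mgp (6.66) and Aspn (5.82), the transporter Slc47a1 (6.21) and the neuropeptide Nmu (adjusted p = 4.53e-09). Higher in the hypothalamus were Pmch, melanin-concentrating hormone (−7.15 ± 0.17), Gad1 (−6.56), Glra2 (−6.33), Sst (−5.54), Avp (−5.39), Dlx1 (−5.27), Rasgef1c (−5.24), Gabra5 (−5.14), Cck (−5.12) and Omg, at least 31.1-fold. Gnrh1 was also higher there (−1.59 ± 0.22). In these controls Ahr (2.79 ± 0.15, adjusted p = 8.91e-09) and Cyp1b1 (4.09 ± 0.32) were higher in the pituitary, Hdac1 was higher (1.70) and Hdac2 lower (−0.42), while Nqo1 (0.09 ± 0.11) did not pass and Cyp1a1 and Ahrr lay below background in both.

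By group, 10 of 12 gonadotroph genes were higher in the pituitary (median 2.89, camera adjusted p = 0.00129), 9 of 13 other anterior pituitary genes adjusted over the list alone (2.29, 0.0104), 15 of 17 mesenchyme and bone markers (3.96, 5.61e-06), and 24 of 25 cell cycle genes (1.54, 1.06e-07). Blood (1.18), endothelial (1.15) and microglia (1.73) markers were higher there by camera as well. Lower were 25 of 32 neuropeptide and transmitter genes (−2.72, 3.01e-06), 12 of 14 neuron markers (mean −2.06, 9.02e-04), 15 of 16 cholesterol synthesis genes (−1.40, 1.77e-04), 8 of 13 hypothalamic transcription factors (−1.99, 0.0336) and 6 of 8 forebrain markers (−2.12, 0.0145). With an estimated correlation none of the 23 lists passed, and the lowest adjusted p was 0.112. By fry, 22 of the 23 passed. In total 9053 probes passed, 4384 higher in the pituitary and 4669 higher in the hypothalamus.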

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

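The tests of the difference and the counts of regroupings were planned, and the bound on ganglion markers was set before its value was seen, while the other tests weighed below were chosen only after the result was seen.

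Each value in this paragraph is a result whose TCDD effect differed between pituitary and hypothalamus in a direct test of that difference (log2, pituitary minus hypothalamus). In all 26 probes differed, 16 of them upward. Upward were the AhR targets Cyp1a1 (6.28), Ahrr (4.02), Nqo1 (1.34), Ugt1a6 (1.66) and Cyp1a2 (0.86), and also Alox15 (2.58), Aldh1a1 (2.47) and the myosin gene Myh7 (2.38). Further upward were Or5m8 (1.75), Bloc1s1 (1.51), the potassium channel genes Kcnc2 (0.87, and 0.52 with adjusted p = 0.297 by a second probe) and Kcnh6 (0.82), Fetub (1.26), Hrk (0.89), Slc40a1 (1.05) and the unnamed probe ILMN_1357002 (1.20). For Slc40a1 (0.40 in the pituitary and −0.65 in the hypothalamus) and ILMN_1357002 (0.08 and −1.12) the difference rests mainly on a negative hypothalamus estimate. ILMN_1357002 was not above background on any pituitary array. Downward were the gonadotropin genes Fshb (−3.36) and Lhb (−1.86), the mast cell proteases Tpsab1 (−3.28) and Mcpt10 (−1.36), and Dapl1 (−1.66), Sdf2l1 (−0.93), Mlc1 (−1.29), Tnnt3 (−0.91), Ces1c (−1.06) and Rbp7 (−0.90). The values of genes below background in a group, such as Cyp1a1, are fitted values and not bounds. Fshb, Mcpt10 and Rbp7 were not above background on any hypothalamus array, and Tpsab1 and Ces1c on 1 each. A fall of these genes could not be measured there, so their differences do not show that the hypothalamus responded otherwise. Among lists the median difference was 1.34 for AhR targets, −0.32 for cell cycle genes and −0.82 for skeletal muscle markers. The last 2 lost their call with an estimated correlation (adjusted p = 0.600 and 0.135), and by fry they gave adjusted p = 0.204 and 0.0195.

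Chance as the source of the 26 probes is not excluded: of 100 drawn from the 200 regroupings of the arrays, 5 passed as many, the real one included, and the highest of the others passed 35. All 5 kept the real division of the pituitary arrays, as 12 of the 100 did, and the highest with another pituitary division passed 2. Those 5 still hold the real pituitary contrast, so their count cannot decide the question. For the pituitary (87 probes), the hypothalamus (3) and the control tissues (9053) the 10 splits of 6 arrays are too few for a share under 0.05. In each, 1 split, the real one, passed as many, and the highest other split passed 1, 1 and 0.

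The first pattern weighed is the rise of AhR targets in the pituitary, where Cyp1a1 and Ahrr were not above background in the hypothalamus. Whether TCDD acted in the hypothalamus stays open: Cyp1b1, the largest of 7 AhR target estimates, was 2.04 higher there, with the lowest TCDD array (8.71) above the highest control (7.57), but it did not pass over all probes (adjusted p = 0.111, within 0.0291 to 0.507 over all alternatives), was 0.79 with the authors' values, and the AhR list did not pass (adjusted p = 0.114, and 0.868 with an estimated correlation). Pituitary tissue in the TCDD hypothalamus samples as the source of that Cyp1b1 difference is argued against: 35 probes far brighter in the pituitary had a median rise of 0.063, where the 4.98% share that Cyp1b1 would need predicts 1.79 (lower quartile 1.62). Tshb averaged 6.24 against a predicted 10.56 and Cyp1a1 4.95 against 7.29. That the lower Ahr level of the hypothalamus (2.79 below the pituitary in controls) limits its response stays open as a hypothesis, since 2 tissues cannot part it from any other difference between them.

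The second pattern is the lower level of skeletal muscle markers in TCDD pituitaries. Dilution by other RNA in TCDD replicate 5 is argued against, since without that array the median was −0.66. A varying share of attached muscle stays open: within groups the 10 markers varied together, with a median correlation of 0.46 across 6 arrays, above 99.8% of 10000 random lists. A TCDD effect on muscle gene expression (median −0.60) stays open too, because a dissection difference between the groups would look alike. Myh7 (2.51) and Myh6 (1.31), myosins of slow and cardiac muscle, rose in the same samples, and Myh6 was named after its value was seen.

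The third pattern is pituitary TCDD replicate 5, in which 220 genes lay more than 1 log2 unit above the mean of the other 5 pituitary arrays. Any other array had 13 to 29. That mean includes controls, so genes raised by TCDD, such as Cyp1a1 (3.52), are counted as well. Among the 220 are Scn10a (4.29 above the mean of the others), Sncg (4.03), Prph (3.47), Scn11a (3.36) and Tac1 (3.10). These are genes of sensory neurons, which were read before any test was set. On the low side 40 genes lay more than 1 log2 unit below the mean of the others, where any other array had 16 to 35. The lowest were Ptgds (−2.85), Tnnt2 (−2.47) and Slc22a6 (−2.40). An untreated sample under a TCDD label is argued against by Cyp1a1, 6.08 above the highest control, and hypothalamic tissue by 12 hypothalamus genes, whose median excess was 0.077 where the 26.3% share that the neuron markers need predicts 3.26, although Slc17a6 (3.03) reached its predicted 2.83 and Tac1 and Adcyap1, which sensory neurons also express, had been left out (with Adcyap1, median 0.096, SD 1.09, lower quartile of predictions 2.72). RNA of sensory ganglion cells, such as those of the trigeminal ganglion beside the gland, stays open: 4 of 16 markers could be tested, with a median excess of 0.46 (SD 0.71), above 98.95% of random lists, short of the excess of 1 set in advance and under the exclusion bound of 0.5 by less than its SD, a condition added after the value was seen. Schwann cell markers, of which Ngfr (2.23) had been seen before, had a median excess of 0.47 over 4 genes, above 99.14% of random lists. The ganglion markers were also higher in TCDD pituitaries as a list (median 0.55, camera adjusted p = 4.13e-04, and adjusted p = 0.0219 with an estimated correlation). That test includes TCDD replicate 5, whose sensory neuron genes prompted the list, and it is not given without that array. It is therefore no independent support. In TCDD replicates 1 and 2 Gfra3 (8.38 against 7.78), Htr3a (10.73 against 10.24) and Runx1 (7.23 against 6.86) averaged above controls.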

How the results depend on the processing

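All settings were planned except the list counts without pituitary TCDD replicate 5, the ganglion, Schwann cell, mast cell and retinoid lists, and the hypothalamus gene set with Adcyap1, which are tests chosen only after the result was seen. The 87 pituitary probes became 218 with the authors' values (80 shared, 94 higher and 124 lower), 231 with array weights (87 shared), 39 with a replicate block (30 shared) and 26 with the tissues normalized and fitted separately (25 shared), and 43 to 92 on leaving out 1 array. For TCDD effects the block joined arrays of a tissue with the same replicate number. Pituitary control replicate 3, pituitary TCDD replicate 5, hypothalamus control replicate 5 and hypothalamus TCDD replicate 4 had no partner and did not inform those effects. The 3 hypothalamus probes became 0 by limma without background correction (1426 at an unadjusted p below 0.05), with the authors' values (1295), with the block (1803) and fitted separately (1001), 1 with median scaling, and 0 to 16 on leaving out 1 array, with 0 without hypothalamus control replicate 3 (986) and 16 without control replicate 5. The 26 differing probes became 43 with an intensity trend and robust variances, 11 with the block (6 shared), and 10 to 32 on leaving out 1 array. The 9053 tissue probes stayed within 6475 to 9514. Other settings kept counts within 1.5 times, and the cause of each change was not tested.

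On leaving out 1 array, 266 pituitary list values and 713 gene values were counted as unchanged. Those called in both settings kept call and direction, and their size was not compared. Those called in neither stayed within a standard error of the main estimate, for lists the median standard error over probes. Of the list values 8 moved or gained a call and 2 lost it, and of the gene values 55 lost the call, 8 moved and 4 gained it. In the hypothalamus the mesenchyme and bone list passed upward (median 0.15, adjusted p = 0.0469) without control replicate 3, where all arrays gave a camera direction downward, and it ranged from −0.19 to 0.15 on leaving out 1 array. With the authors' values Nfe2l2 (adjusted p = 0.0106), Plk1 (0.0120), Mcm5 (0.0143), Ttk (0.0315) and Dlat (0.0411) passed over all probes in the pituitary. Median scaling moved the median of all hypothalamus probes by −0.09. With the block the pituitary calls of Serpina3c (adjusted p = 0.281), Tpsab1 (0.106), Rxrg (0.130), Pcsk2 (0.213), Sdf2l1 (0.237), Tnnc2 (0.0740) and Tnnt3 (0.350) were lost, as were the difference calls of Bloc1s1 (0.0932), Mcpt10 (0.199), Tpsab1 (0.224), Dapl1 (0.0862) and Lhb (0.108), and Ibsp passed in the pituitary (0.0186). Whether replicate numbers pair the samples is not known. In deviations from the group means, treatments with the same number in a tissue correlated at −0.07 to 0.11. Tissues with the same number and treatment correlated at −0.02 to 0.02. As the dams were the treated animals, a control and a TCDD sample cannot share a dam or litter. For tissues of the same treatment, so few correlations cannot tell whether samples share a dam or litter. Authors' values were not used for the comparison of the control tissues, as they were normalized within each tissue, and separate fits give no contrast between tissues. A BeadChip block was not run, as the files name no chip. Signal near background limits Cga, Kiss1 and, in controls, Cyp1a1 and Ahrr.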

Other observations

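The genes and lists in this part were chosen only after the result was seen, and so were their tests.

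Beside the mast cell proteases Tpsab1 and Mcpt10, the other mast cell proteases tested did not pass: Tpsb2 (−1.08, adjusted p = 0.157), Cpa3 (−0.61, 0.579), Cma1 (−0.73, 0.660) and Mcpt1 (−0.12, 0.884). A test of mast cell markers as a list is not given, because the list was written after those 2 genes had passed and holds them. Retinoid pathway genes moved both ways: of 12 tested, Aldh1a1 (1.98) and Rxrg (0.77) rose and Rbp7, a retinol-binding protein, fell at least 1.35-fold, to below background, with a median of −0.00, also with Rbp7 at its bound. That list too was written after called genes had been seen, and its test is likewise not given.

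Other pituitary calls belong to several groups. Receptor and signalling genes included Mtnr1a, a melatonin receptor, which fell by 0.87 (adjusted p = 0.0279), Bambi, a pseudoreceptor of the TGF-β family, which fell by 0.71 (0.0468), and Gipr, an incretin receptor, which rose by 1.04 (0.0220). The cell cycle genes Ube2c (−0.60) and Cdt1 (−0.68), which were on no fixed list, fell. Endothelial genes Esm1 (0.64) and Acvrl1 (0.98) rose. The chemokine Ccl2 rose by 0.72, while the chemokine Ccl5 (−0.64) and the macrophage receptor Cd163 (−0.64) fell. Ion channel genes Kcnh6 (0.65) and Asic4 (1.01) and the channel subunit gene Dpp6 (at least 1.38-fold, from below background) rose, as did the transcription factor Sox14 (1.04).

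Ttr, a transcript abundant in choroid plexus, had a log2 level of 12.51 in pituitary control replicate 1 and 11.80 in hypothalamus TCDD replicate 3, and 5.05 to 6.49 on the other 10 arrays.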
